A study of Mus musculus with 2 samples.

How the data were processed

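Brown adipose tissue was frozen, RNA was extracted and treated with DNase, and libraries were made from polyadenylated RNA that was fragmented, copied into cDNA and amplified by PCR, per the labels' protocols. The protocol does not mention strand, so reads of a gene and of an overlapping antisense partner are not separated here. There were 2 libraries, 1 with floxed D3B alleles and 1 with floxed D3B alleles and the Ucp1-driven Cre, both from mice of 45 weeks. The female sex comes from the title of the series. D3B is taken as Dnmt3b from knowledge of the study, since the labels do not spell it out. The labels give neither the number of mice in a library nor the time of day of collection. The lane is read from each library's run name, and each genotype had its own lane.

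The authors deposited, for each library, 1 line per gene with an Entrez gene identifier, RefSeq transcript identifiers, a transcript length, an expected count and an FPKM value, per the file headers. The submitters' processing notes name RSEM, without a version, and the mouse build mm9. The aligner is not given in the sources used here. The expected count deposited by the authors is an estimate of the reads of a gene in which reads that match several genes are divided among them, so it need not be whole. In the control library 94.0% and in the knockout library 94.1% of the counts were whole to within 0.05. A gene with a count further from whole is called one with shared reads. The deposited FPKM values are fragments per kilobase of transcript, scaled to the size of the library and given to 2 decimals, so the smallest value above 0 is 0.01. They summed to 606888 in the control library and 571034 in the knockout library. Because FPKM is relative to the whole library, abundant genes shift all others. The 20 most abundant genes took 10.8% of the control counts and 11.6% of the knockout counts, and the top gene 2.23% and 3.28%.

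Only genes with a value are listed in a library. Together the libraries list 16174 genes, of which 14744 are in both, 684 in the control alone and 746 in the knockout alone. A gene not listed was set to 0. Symbols came from a RefSeq gene table of the assembly GRCm38.p6 by Entrez identifier, with 16134 genes matched. This assembly differs from mm9, so no coordinates are printed. GC content was the mean over a gene's RefSeq transcripts as paired with GENCODE M21 transcripts and was known for 98.7% of tested genes.

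With 1 library per group no test between genotypes is possible, and no p-value is given. A fixed rule of size took its place. A gene was tested when it had at least 1 FPKM in either library. It was counted as higher or lower when log2((FPKM + 1) in the knockout / (FPKM + 1) in the control) was at least 1 or at most -1 and the 95% interval of the ratio excluded 1. The pseudocount of 1 makes this scale understate the difference of genes with low values. The ratios in the text are ratios of FPKM without pseudocount. Their intervals are exact conditional Clopper-Pearson intervals of the rounded expected counts. They cover counting error only and compare these 2 libraries, not the genotypes. A count of 3, the limit that a count of 0 allows, was worth 0.310 CPM (counts scaled to library size) in the control library and 0.298 CPM in the knockout library.

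Gene lists were written before the data were examined: 45 lists of pathways, complexes, cell types and cell states. The member counts at 1.5-fold are on the same log2 scale. Each list with at least 5 tested members was given the percentile of its median log2 ratio among 10000 random lists of the same size, drawn from 20 expression bins of equal size. A list was said to stand apart below the 2.5 or above the 97.5 percentile. The oxidative phosphorylation list joins the complex I, complexes II to IV and ATP synthase lists. Some genes belong to more than 1 list, so lists are not independent. The genes named were fixed by a rule before the data were examined. The rule always took Dnmt3b, Dnmt1, Dnmt3a and Ucp1. It added the 10 genes with the largest and the 10 with the smallest log2 ratio that met the rule of size with at least 10 FPKM in the higher library, and up to 4 members of each list with the largest absolute log2 ratio. Genes outside the rule are said to be chosen after their values were seen. For 1 list, a member that the rule allows is not reported here.

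The alternatives planned before were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, folds of 1.5 and 4, CPM in place of FPKM, 3 rescalings of FPKM (median log2 ratio set to 0, each library rescaled to the same FPKM total, and the same without the 20 most abundant genes), marker genes of muscle, blood and immune cells left out, the mean in place of the median, 50 expression bins, and random lists matched on length. Further alternatives were chosen after seeing the data, when the log2 ratio was found to vary with length and GC content. A smooth trend with length, GC content and expression was fitted on 7203 genes outside the oxidative phosphorylation, ribosomal and thermogenic lists and subtracted, and random lists were matched jointly on 4 expression, 5 length and 5 GC classes. A list of glucocorticoid-responsive genes and 2 arms of the clock were also added then.

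The calculations were tested on simulated counts for the 11746 tested genes of this comparison with 200 changed genes. The rule found 86% of genes changed 3-fold and 93% of those changed 4-fold, and called 1 of 11546 unchanged genes. The counting intervals held the true ratio for 95.7% of genes. The simulated counts held counting error alone, without spread between mice, libraries or lanes. The 1 call among 11546 genes is therefore not the rate of false calls in the real pair. Of 100 simulated lists without a shift, 9 lay outside the 2.5 to 97.5 percentiles, so a list close to these limits is weak evidence. A known length trend was recovered with a median error of 0.0082 on the log2 scale. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.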

Results

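Gene expression was measured by RNA sequencing in brown adipose tissue, the heat-producing fat depot, from female C57BL/6 mice kept on chow until 45 weeks of age. The comparison had 1 library per genotype. The control library came from mice with floxed D3B alleles. The knockout library came from mice that carried in addition a Cre recombinase driven by the promoter of Ucp1, a gene of brown adipocytes, so that the allele is cut in these cells. D3B is read here as Dnmt3b, the gene of a DNA methyltransferase that sets methyl groups on unmethylated DNA. The control library held 9666528 expected counts over 15428 listed genes, and the knockout library held 10068359 over 15490. With no replicates there is no estimate of the spread between mice, and the difference between the libraries has no replicate check. Each interval given after a ratio is a 95% counting interval and covers counting error only. It treats every read as an independent molecule, so with reads copied by PCR it may be too narrow even for that. The libraries were run on different sequencer lanes, control on lane 2 and knockout on lane 1, so lane and genotype cannot be told apart. The label of the control names no Cre, so the Cre transgene and the loss of D3B cannot be told apart either.

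The first question was whether the targeted transcript was lower in the knockout library. Dnmt3b (Entrez gene 13436) was at 0.39 FPKM in the control library and 0.18 FPKM in the knockout library. These values rest on 15 and 7 expected counts, and the knockout to control ratio of 0.46 had an interval of 0.16 to 1.20 that included 1. A lower Dnmt3b level was therefore not detected, and the interval leaves room for a strong loss as well as for none. The gene-level value includes exons outside the deleted part and transcripts of cells without Cre, so it is a weak check of the labels. Dnmt1 (13433), the maintenance methyltransferase, was at 3.69 FPKM in the control and 3.56 FPKM in the knockout library, a ratio of 0.96 (0.79 to 1.19). Dnmt3a (13435), the other de novo methyltransferase, was at 3.43 and 3.23 FPKM, a ratio of 0.94 (0.80 to 1.11). Over the 18 tested genes of the DNA methylation machinery the median log2 ratio of knockout to control was -0.02, at percentile 46.9 among 10000 random gene lists matched on expression. The mean of these genes had the opposite sign, 0.06. Gadd45b, a stress-induced gene linked to DNA demethylation, was the list member past 2-fold on the log2(FPKM + 1) scale. It was at 4.52 FPKM in the knockout library against 1.73 FPKM, a ratio of 2.61 (1.56 to 4.54). Mbd4, a glycosylase that repairs mismatches at methylated sites, was lower at 0.57 FPKM against 1.29 FPKM, a ratio of 0.44 (0.24 to 0.75).

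Across the 11746 genes with at least 1 FPKM in either library, 106 were at least 2-fold higher and 79 at least 2-fold lower in the knockout library. The gene with the largest positive log2 ratio among well-expressed genes was Fkbp5, a co-chaperone of steroid receptors, at 14.8 FPKM against 3.12 FPKM, a ratio of 4.73 (3.87 to 5.83). Next on that scale came Gsta3, a glutathione transferase, with a ratio of 4.07 (3.11 to 5.39), and Mest, an imprinted gene linked to fat expansion, with 3.20 (2.85 to 3.59). Zbtb16, a transcription factor, had a ratio of 3.15 (2.75 to 3.62), and the matrix-associated genes Ccn2 and Fn1 had ratios of 3.36 (2.67 to 4.28) and 2.96 (2.70 to 3.26). Ubd, an interferon- and TNF-induced ubiquitin-like modifier, had a ratio of 2.85, the complement gene C4b 2.65, the meiotic gene Sycp3 2.79 and the macrophage product Retnla 2.45. The C4b value is uncertain, because its counts were not whole and so include reads divided between near-identical genes. In the other direction, the immediate early genes Nr4a1 and Egr1 stood at 0.133 (0.113 to 0.155) and 0.240 (0.195 to 0.295) of their control level. Cfd, which encodes the adipokine adipsin, was at 473 FPKM in the knockout library and 1591 FPKM in the control library, a ratio of 0.297 (0.287 to 0.308). Irs2, an adaptor of the insulin receptor, had a ratio of 0.268 (0.220 to 0.325), and the transcription factor Klf2 0.313 (0.275 to 0.355). The remaining genes of this group were Cox6b2 with a ratio of 0.297, Dusp4 with 0.327, Rgs2 with 0.340, Erdr1 with 0.341 and the imprinted cell cycle inhibitor Cdkn1c with 0.352.

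**Figure D1:**
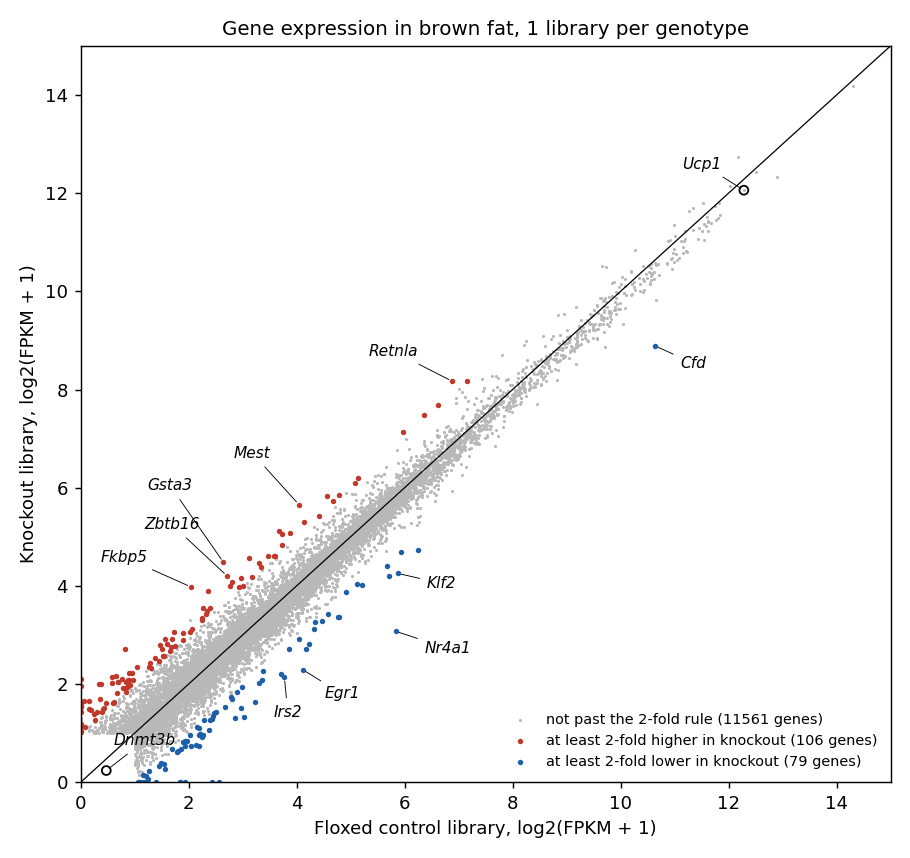
Each point is 1 gene, with log2(FPKM + 1) in the control library on the x axis and in the knockout library on the y axis. Red points mark the 106 genes at least 2-fold higher and blue points the 79 genes at least 2-fold lower in the knockout library, grey points the other tested genes, the line equal values, and open circles Ucp1 and Dnmt3b, the latter below the level needed for testing.

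Most genes differed little between the libraries: 91.7% of tested genes were within 1.5-fold, the median log2 ratio was -0.03, and Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.985. A further 15 genes were past 2-fold but had a counting interval that included 1, and 35 of the genes past the rule had counts that were not whole. The balance of the counts depended on scaling, with 210 higher and 95 lower genes after both libraries were rescaled to the same FPKM total, and 228 and 100 when the 20 most abundant genes were also left out of the total. After removal of the trend with transcript length, GC content and expression, an alternative chosen after seeing the data, the counts were 144 higher and 54 lower.

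Genes that mark thermogenic brown adipocytes were lower as a group in the knockout library. Bulk tissue does not tell a lower level per cell from a lower share of brown adipocytes. Of 35 tested members, 29 had a log2 ratio below 0, 7 were at least 1.5-fold lower and 1 was at least 1.5-fold higher. The median log2 ratio was -0.22, at percentile 0.07 of the matched random lists, whose medians spanned -0.16 to 0.04 in their central 95%. Ucp1 (22227), the uncoupling protein that lets brown mitochondria release heat, was at 4271 FPKM in the knockout library against 4987 FPKM in the control library. Its ratio of 0.857 (0.848 to 0.865) was well inside the 1.5-fold range. Irf4, a cold- and fasting-responsive regulator, had a ratio of 0.333 (0.248 to 0.443), and Eva1a had 0.327 (0.186 to 0.551). Slc27a2, a fatty acid transporter, was lower with a ratio of 0.599 (0.558 to 0.642), while Elovl3, an enzyme that lengthens fatty acids, was higher with 1.65 (1.46 to 1.87). Other brown fat genes, chosen after their values were seen, were Dio2, which activates thyroid hormone, with a ratio of 0.620 (0.571 to 0.674), Cidea with 0.817 (0.804 to 0.831), Ppargc1a with 0.812 (0.735 to 0.896) and Prdm16 with 0.903 (0.763 to 1.07).

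Nuclear genes for the respiratory chain were lower by a small amount. Of the 79 tested oxidative phosphorylation genes 74 had a log2 ratio below 0, and none reached 1.5-fold in either direction. Their median log2 ratio was -0.26, below all 10000 random lists, whose central 95% was -0.14 to -0.04. With both libraries rescaled to the same FPKM total it was -0.17, again below all random lists. Complex I genes had a median of -0.27, also below every random list, and those of complexes II to IV had -0.26 at percentile 0.17 and at 1.95 against lists matched on length. The ATP synthase subunits, with a median of -0.15, lay at percentile 22.96 and inside the range of random lists. Ndufs6 and Ndufs7 of complex I had ratios of 0.691 (0.656 to 0.728) and 0.695 (0.667 to 0.724), Uqcr11 of complex III 0.757 (0.732 to 0.782) and Cox6c of complex IV 0.758 (0.740 to 0.777). Mitochondrial ribosomal proteins were likewise lower, with 61 of 76 genes below 0 and a median of -0.18, below all random lists matched on expression but at percentile 2.33, close to the limit, against lists matched on length. In this list Mrpl21 had a ratio of 0.753 (0.647 to 0.877) and Mrpl19 0.736 (0.633 to 0.853).

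The log2 ratio also varied with the transcript itself. Across the 7534 genes with a mean of at least 5 FPKM, its Spearman correlation was 0.24 with transcript length and -0.24 with GC content. The shortest 10% of these genes had a median log2 ratio of -0.19 and the longest 10% 0.06. Oxidative phosphorylation genes are short, with a median length of 679 bases against 2682 over all tested genes, and mitochondrial ribosomal genes have a median of 1052. After the trend was removed, by an alternative chosen after seeing the data, the oxidative phosphorylation median was -0.13, still below all random lists, with -0.14 at percentile 0.02 for complex I and -0.16 at 0.06 for complexes II to IV. The mitochondrial ribosomal median was -0.08 at percentile 0.76, and the thermogenic median -0.17, again below all random lists. Cytosolic ribosomal proteins had a median of -0.16 at percentile 3.63 as deposited, inside the range of random lists, and -0.06 at percentile 35.01 with the trend removed. Their mean of -0.16 was outside the range at percentile 0.29, and so was the median against lists drawn with no filter on low values, at percentile 1.51.

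**Figure D2:**
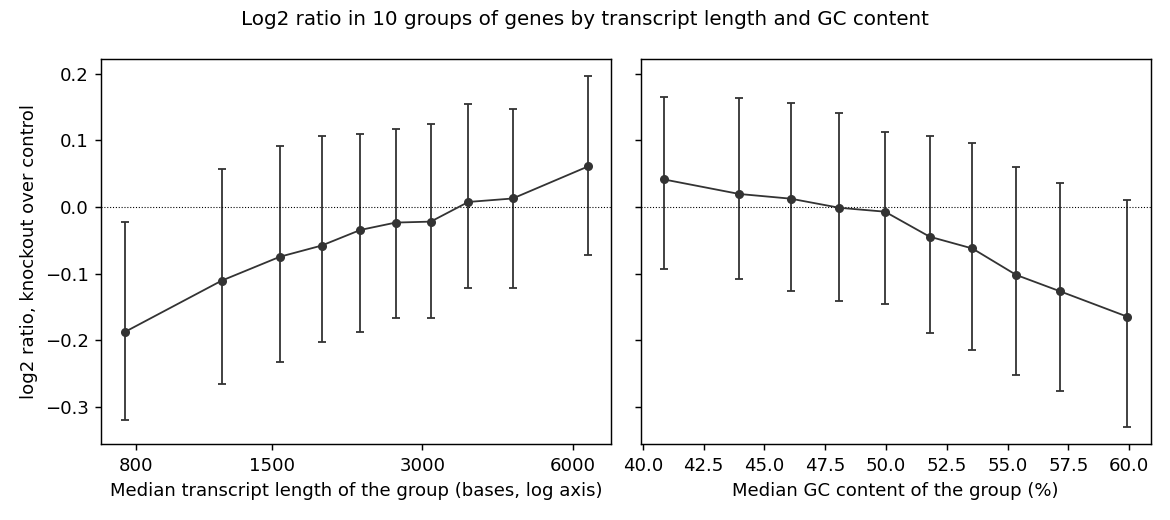
Points give the median log2 ratio of knockout to control in 10 groups of about equal size of the 7534 genes with a mean of at least 5 FPKM, ordered by transcript length in bases (left, log axis) or by GC content in percent (right, genes with a known GC content), and bars span the lower to the upper quartile of the genes. The median runs from -0.19 in the shortest to 0.06 in the longest group, and from 0.04 at the lowest to -0.16 at the highest GC content.

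Lipid-synthesizing genes were shifted towards higher values in the knockout library, though not all of them. Among 28 tested genes of de novo lipogenesis and triglyceride synthesis, 17 had a log2 ratio above 0 and 11 below, 5 were at least 1.5-fold higher and none at least 1.5-fold lower, and the median of 0.17 exceeded all random lists. For the 26 of them with a mean of at least 5 FPKM the median was 0.09 at percentile 99.9. The 5 were Acly, which makes cytosolic acetyl-CoA, with a ratio of 1.86 (1.82 to 1.91), the fatty acid synthesis enzymes Acaca with 1.83 (1.79 to 1.88) and Fasn with 1.82 (1.81 to 1.84), the NADPH-producing Me1 with 1.71 (1.64 to 1.78) and the desaturase Scd2 with 1.65 (1.54 to 1.78). Scd2 was named after its value was seen, as was the far more abundant Scd1, at 6827 FPKM against 4634 FPKM with a ratio of 1.473 (1.465 to 1.481). Reads of Scd1 were in part shared with other genes. Glucose uptake and glycolysis genes had a median of 0.19, above all random lists, with 20 of 29 genes above 0 and a smaller mean of 0.10 at percentile 99.6. Pygl, a glycogen phosphorylase, had a ratio of 1.51 (1.46 to 1.56) and Pfkfb1, which sets fructose 2,6-bisphosphate levels, 0.553 (0.477 to 0.640). Cholesterol synthesis genes had a median of 0.18 at percentile 99.9, with Nsdhl at a ratio of 1.60 (1.39 to 1.85). That call ended when the pseudocount was 5 or the mean of the list was used in place of its median.

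Fat-burning and fat-storing genes showed no shift past random lists as deposited. Fatty acid oxidation genes had a median of -0.12 at percentile 27.2. With the length and GC trend removed the same list, still at -0.12, was outside the range at percentile 0.72. Acaa1b had a ratio of 0.660 (0.590 to 0.739), Fabp3 0.703 (0.687 to 0.719) and Cpt1a, which admits fatty acids to mitochondria, 1.47 (1.26 to 1.71). Lipolysis and lipid droplet genes had a median of -0.03 at percentile 87.9. Their mean was 0.02, and with the trend removed the median was 0.07 at percentile 97.96. G0s2, an inhibitor of lipolysis, had a ratio of 0.698 (0.671 to 0.726), and Plin4, a lipid droplet coat protein, 1.42 (1.38 to 1.46). The citric acid cycle list had a median of -0.05 at percentile 89.2, and its mean of 0.03 had the opposite sign. Mitochondrial biogenesis and dynamics genes had a median of -0.08 at percentile 36.2. Creatine and calcium cycling genes had a median of -0.05 at percentile 53.1, among them the creatine kinase Ckb with a ratio of 0.550 (0.497 to 0.609).

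PI3K-Akt signalling, which carries the insulin signal, was compared because the study is known to have followed it in these mice, so this list is not independent evidence of a direction. The 45 tested core genes were not shifted as a group. Their median log2 ratio was 0.01 at percentile 79.9, their mean was -0.04, and 23 lay above and 22 below 0. On the log2(FPKM + 1) scale the insulin receptor substrates were the members past 2-fold. These were Irs2, as given above, and Irs1 at 1.45 FPKM against 4.4 FPKM, a ratio of 0.330 (0.269 to 0.402). Trib3, a pseudokinase that binds Akt, was at least 1.5-fold lower with a ratio of 0.532 (0.424 to 0.666). On the log2(FPKM + 1) scale the member at least 1.5-fold higher was Pik3ap1, an adaptor of immune cells, with an FPKM ratio of 2.28 (1.26 to 4.29). The Akt genes themselves, chosen after their values were seen, had ratios of 1.02 (0.93 to 1.12) for Akt1 and 0.852 (0.822 to 0.882) for Akt2. Ligands and receptors that act on the pathway had a median of 0.14 at percentile 99.98, with 10 of 57 genes at least 1.5-fold higher and 4 at least 1.5-fold lower. Pgf had a ratio of 3.89 (2.02 to 8.23), Fgf13 3.0 (2.15 to 4.24) and the imprinted growth factor Igf2 0.361 (0.267 to 0.483). This call depended on the filter for low values. The 24 members with a mean of at least 5 FPKM had a median of -0.10 at percentile 13.9. With no filter on low values the median of 77 members was 0.01 at percentile 67.0.

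Extracellular matrix genes were higher in the knockout library. Of 55 tested collagens, laminins, integrins and other matrix genes, 48 had a log2 ratio above 0, 18 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. Their median of 0.38 exceeded all random lists. Fn1 has been given above. Eln, the elastin gene, had a ratio of 2.13 (1.79 to 2.54) and Thbs2 2.15 (1.80 to 2.59). Thbs4 had 60 counts in the knockout library and was not listed in the control library. Genes of fibroblasts and preadipocytes had a median of 0.29, again above all random lists, with 7 of 23 at least 1.5-fold higher. Mfap5 had a ratio of 2.31 (1.88 to 2.84), Fbn1 1.83 (1.64 to 2.03) and Col1a1 1.72 (1.59 to 1.87). Of these 23 genes 9 also belong to another list, the matrix list among them. Pericyte and smooth muscle genes had a median of 0.22 at percentile 99.9, with 11 of 15 above 0 and 4 below. Acta2, the smooth muscle actin, had a ratio of 2.10 (1.81 to 2.43) and Synpo2 2.58 (2.11 to 3.19), while Kcnj8 was lower with 0.664 (0.571 to 0.772). Pdgfrb with 0.728 (0.636 to 0.832) and Des with 0.691 (0.620 to 0.769), both chosen after their values were seen, were also lower. The list median therefore does not stand for all of its markers.

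Genes that are associated with white adipocytes showed the largest median of the lists with a percentile. Of 15 tested genes 12 were at least 1.5-fold higher and none at least 1.5-fold lower, and the median log2 ratio of 0.85 exceeded all random lists. Besides Mest, the genes with the largest differences on the log2(FPKM + 1) scale were Dpt with a ratio of 2.22 (2.07 to 2.37), Nnat with 2.12 (1.97 to 2.28) and the amino acid transporter Slc7a10 with 2.16 (1.82 to 2.56). In the control library 14 of these 15 genes were already at 1 FPKM or above, and 6 belong to another list as well. Adipokines and general adipocyte genes were not shifted as a group, with a median of -0.10 at percentile 30.3. Within that list Cfd was lower, as given above, Lep, the leptin gene, was at 256 FPKM against 128 FPKM with a ratio of 2.0 (1.92 to 2.08), Adrb1 had a ratio of 0.528 (0.422 to 0.657) and Adig 0.649 (0.611 to 0.689).

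Macrophage and monocyte genes were higher throughout. All 29 tested genes had a log2 ratio above 0, 15 were at least 1.5-fold higher, and the median of 0.61 exceeded all random lists. On the log2(FPKM + 1) scale the largest differences apart from Retnla were in Lyve1 with a ratio of 3.40 (2.46 to 4.79), which also marks lymphatic endothelium, Lgals3 with 2.09 (1.87 to 2.35) and Cd9 with 2.07 (1.65 to 2.61). Endothelial genes pointed the other way, with 17 of 26 below 0, 6 at least 1.5-fold lower and 1 at least 1.5-fold higher, but their median of -0.12 at percentile 4.80 stayed inside the range of random lists. It left that range with the mean of the list, -0.19 at percentile 0.53, and with the 19 genes at a mean of at least 5 FPKM, -0.15 at percentile 2.43. It also did so with muscle, blood and immune marker genes left out, -0.15 at percentile 1.80. That setting takes the list from 26 to 25 genes by dropping Lyve1, its member at least 1.5-fold higher. Aplnr had a ratio of 0.237 (0.172 to 0.321), the tight junction gene Cldn5 0.495 (0.444 to 0.552) and Egfl7 0.557 (0.498 to 0.622). The list of neutrophil, mast cell and eosinophil genes had a median of 0.17 at percentile 94.8. It was outside the range with no filter on low values (percentile 99.4), with the length and GC trend removed (98.8), with the mean of the list (98.6) and against lists matched on length (98.03). Of its 11 genes 7 were above 0 and 4 below. S100a8 had a ratio of 2.44 (1.25 to 5.06) and Ear2 2.08 (1.467 to 2.998), while Mcpt4 was lower with 0.582 (0.399 to 0.839).

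**Figure D3:**
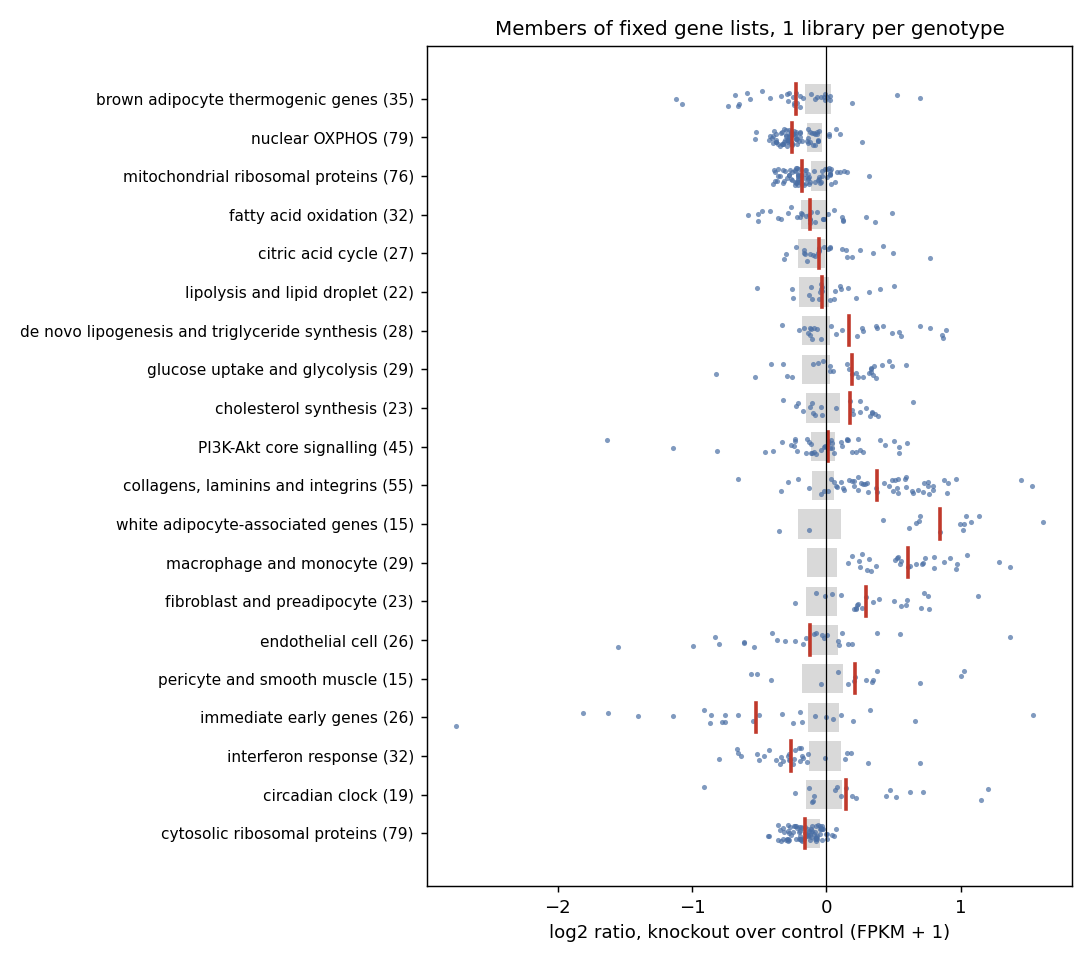
Points are the tested members of 20 gene lists (number of genes in parentheses), placed by their log2 ratio of knockout to control (x axis), red bars are list medians, and grey boxes span the central 95% of medians of 10000 random lists matched on expression. The white adipocyte-associated median of 0.85 and the macrophage median of 0.61 lie to the right of their boxes, and the immediate early gene median of -0.52 and the oxidative phosphorylation median of -0.26 to the left.

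Immediate early genes, which are switched on within minutes of a stimulus, were lower in the knockout library. Of 26 tested genes 12 were at least 1.5-fold lower and 2 at least 1.5-fold higher, and the median of -0.52 lay below all random lists. Nr4a1, Egr1 and Klf2 were lower and Ccn2 higher, with the values given above. Interferon response genes were lower too, with 27 of 32 below 0 and a median of -0.26, below all random lists. Irf7, a regulator of the response, had a ratio of 0.519 (0.384 to 0.695), Usp18 0.522 (0.326 to 0.822) and Isg15 0.606 (0.429 to 0.851), while Ifi204 was higher with 1.81 (1.349 to 2.431). The circadian clock list had a median of 0.14 at percentile 98.9. Per2 had a ratio of 2.68 (2.22 to 3.24), Ciart 3.0 (1.87 to 4.97) and Dbp 1.68 (1.44 to 1.98), and Arntl, whose cycle runs opposite to theirs, 0.419 (0.294 to 0.591). For the 14 clock genes with a mean of at least 5 FPKM the median was 0.10 at percentile 95.6, which ended the call. Nuclear receptor and hormone signalling genes had a median of -0.16 at percentile 1.36 with 18 of 26 below 0, but the 3 members with the largest differences on the log2(FPKM + 1) scale were higher. These were Fkbp5, Tsc22d3, a glucocorticoid-induced leucine zipper gene, with a ratio of 2.03 (1.85 to 2.24), and Hsd11b1, which regenerates active glucocorticoid, with 1.66 (1.52 to 1.81), against 0.523 (0.375 to 0.722) for the oestrogen receptor Esr1. The call of this list ended with a pseudocount of 5, with no filter, and with the mean of the list, which was -0.03 at percentile 47.8.

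Antigen presentation genes had a median of 0.12 at percentile 99.6, with 11 of 18 above 0 and 7 below. H2-DMb1 and H2-DMa, which load peptide onto class II molecules, had ratios of 1.72 (1.346 to 2.208) and 1.73 (1.31 to 2.30). Tap2 was lower with 0.726 (0.638 to 0.825), so the list did not rise throughout. Oxidative stress and glutathione genes had a median of 0.04 at percentile 99.2. Besides Gsta3, the metallothionein Mt2 had a ratio of 1.66 (1.503 to 1.823) and the plasma peroxidase Gpx3 0.562 (0.550 to 0.574). Both calls were small and ended under at least 1 alternative, at percentile 95.7 for antigen presentation genes with a mean of at least 5 FPKM and at 96.0 for oxidative stress genes against lists matched on length. Inflammatory cytokines and chemokines had a median of -0.05 at percentile 30.9, and their mean of 0.09 had the opposite sign. The 11 genes of this list with a mean of at least 5 FPKM had a median of 0.15 at percentile 98.4. Ccl6 had a ratio of 2.45 (2.15 to 2.81) and Ccl9 2.17 (1.87 to 2.52). Cell cycle genes had a median of 0.16 at percentile 93.8, and 15 of 19 were above 0. With the trend removed, the median of 0.24 was outside the range at percentile 98.5, as was the list with no filter (99.8), with its mean (99.5) and against lists matched on length (99.5). Cdk1 was at 1.41 FPKM against 0.22 FPKM, a ratio of 6.41 (2.70 to 18.5).

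The remaining lists lay inside the range of random lists, and no direction is read from them. Heat shock and chaperone genes had a median of 0.01 at percentile 82.5. Genes of the unfolded protein and integrated stress response had a median of -0.01 at percentile 69.1 and a mean of 0.01, with the serine synthesis gene Psat1 at a ratio of 2.16 (1.79 to 2.61) and Creld2 at 0.567 (0.443 to 0.723). Imprinted genes had a median of -0.04 at percentile 50.9, and their members past 2-fold were Mest and Nnat on the higher side and Cdkn1c and Igf2 on the lower side. Schwann cell and nerve genes had a median of 0.04 at percentile 65.9, erythroid genes -0.08 at 43.1 and skeletal muscle genes -0.18 at 9.22. Fewer than 5 members of the other lists were tested, too few for a percentile. The median of 4 T and NK cell genes was -0.56, and Cd37, the tested B cell gene, had a ratio of 2.98 (1.73 to 5.39). The epithelial and the mammary list had 3 tested genes each and a shared median of -0.65, set in both by the keratin Krt5. Sycp3, given above, was the tested germline gene. The female transcript Xist was at 29.1 FPKM in the control and 27.9 FPKM in the knockout library, and the Y-linked genes Ddx3y and Eif2s3y had 1 count each in the control library and 0 in the knockout library.

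In all, 12 of the 39 lists with a percentile lay above the central 95% of random lists and 7 below it. None of these 19 calls ended and none of their medians changed sign under any of the 4 rescalings of the libraries or with the length and GC trend removed. Their size did depend on the settings, and the values that follow differ by over 1.5 times from those as deposited while the call held. With a pseudocount of 5 the median was 0.25 for matrix, 0.38 for macrophage, 0.13 for pericyte, 0.11 for lipogenesis, 0.09 for clock, 0.07 for antigen presentation, 0.08 for PI3K-Akt ligand and receptor, -0.27 for immediate early and -0.12 for interferon response genes. With both libraries at the same FPKM total it was -0.10 for mitochondrial ribosomal, -0.17 for complexes II to IV, 0.27 for lipogenesis, 0.28 for cholesterol synthesis, 0.23 for clock, 0.23 for PI3K-Akt ligand and receptor, 0.21 for antigen presentation and 0.13 for oxidative stress genes. The same lists differed by over 1.5 times, in the same direction, when the 20 most abundant genes were left out of the total. At a mean of at least 5 FPKM it was 0.11 for cholesterol synthesis genes, and with marker genes of muscle, blood and immune cells left out 0.09 for PI3K-Akt ligand and receptor genes. For oxidative stress genes it was 0.08 with the trend removed, and their mean was 0.11. Their median was also 0.08 when the median log2 ratio of genes with a mean of at least 5 FPKM was set to 0. The mean of the clock list was 0.23, and with a pseudocount of 0.1 the nuclear receptor median was -0.25. The percentiles describe these libraries and do not test the genotype.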

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

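The lower medians of the thermogenic and oxidative phosphorylation lists stayed outside the range of random lists, and the PI3K-Akt core median inside it, under every alternative run. With the mean of the list counted among the alternatives, the values spanned -0.25 to -0.15, -0.26 to -0.13 and -0.04 to 0.09. The numbers of genes past the rule of size depended strongly on the settings. Against 106 higher and 79 lower genes, there were 281 and 196 with a pseudocount of 0.1, 15 and 14 with a pseudocount of 5, 42 and 27 at a mean of at least 5 FPKM, 511 and 401 at 1.5-fold, and 1 and 3 at 4-fold. These follow from how the pseudocount and the thresholds are built. The higher genes numbered 210 with both libraries rescaled to the same FPKM total, 228 with the 20 most abundant genes left out of the total and 179 by CPM, against 95, 100 and 110 lower genes. Rescaling also changes the weight of a pseudocount of 1, and its part in these counts was not tested. The other alternatives left both counts within 1.5 times. Dnmt3b had a log2 ratio of -0.24 as deposited and of -0.81, -0.23 and -0.59 under its 3 alternatives, none of which adds counts to the 15 and 7 it rests on. For the other 37 lists, 482 results under alternatives kept their side of the range, of which 451 kept their sign and 31, inside the range before and after, changed sign or, in 1 case, became 0. These 31 came from 10 lists, among them DNA methylation machinery, the citric acid cycle and lipolysis. A further 11 lost and 14 gained a place outside the range, and 4 reversed. Reversed were the citric acid cycle with the mean of the list (0.034), lipolysis and lipid droplet genes with the length and GC trend removed (0.068), and, at a mean of at least 5 FPKM, PI3K-Akt ligands and receptors (-0.10) and inflammatory cytokines (0.15). For the latter pair the alternative keeps 24 and 11 genes, and otherwise the cause was not tested. Trend removal and joint matching were chosen after seeing the data. No paired analysis was possible because each group has 1 library. For Dnmt3b, with 15 and 7 counts, depth left an interval of 0.16 to 1.20.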

Other observations

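Tests of the share of brown adipocytes, of attached white fat and of the time of day were chosen after the results they bear on were seen, as were the removal of the length and GC trend, the glucocorticoid list and the clock arms. Genes known to respond to glucocorticoid hormone were higher in the knockout library. Of 28 tested genes 8 were at least 1.5-fold higher and 2 at least 1.5-fold lower, and the median log2 ratio of 0.21 exceeded all 10000 random lists. Fkbp5 and Zbtb16 had ratios of 4.73 and 3.15. Serpina3n, an acute-phase protease inhibitor, had a ratio of 2.40 (2.08 to 2.77) and Map3k6 2.21 (1.92 to 2.56). This list was written because Fkbp5 stood out, so its total is not independent of that gene.

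Of the genes past the rule of size, 137 belonged to no list, 73 higher and 64 lower. Those named here were chosen after their values were seen. On the higher side, Slc6a13, a GABA and taurine transporter, had a ratio of 2.63 (2.13 to 3.27), the inhibitory Fc receptor Fcgr2b 2.60 (1.98 to 3.40), Fhl1 2.28 (2.14 to 2.43), the collagen-modifying enzyme P4ha2 2.49 (1.94 to 3.23) and the complement gene Cfb 2.25 (1.97 to 2.57). On the lower side, the transcription factor Hlx had a ratio of 0.343 (0.279 to 0.421), the noncoding RNA Lncbate10 0.400 (0.353 to 0.454), Cyp2e1 0.415 (0.370 to 0.466), the checkpoint ligand Cd274 0.401 (0.347 to 0.462) and the kinase gene Sik1 0.409 (0.362 to 0.461).

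Oxidative phosphorylation genes were lower in the knockout library, with a median log2 ratio of -0.26. Subtracting the trend with length and GC content left -0.13. With 1 library per genotype it cannot be told whether that trend is an effect of library preparation or part of the difference between the mice. As the whole cause it is argued against, because random lists then spanned -0.07 to 0.03. A lower share of brown adipocytes, with the other cell types in fixed proportions, would raise all their markers alike. The macrophage median exceeded the endothelial median by 0.74 (bootstrap interval over 28 and 25 genes 0.53 to 1.03). Both medians were known when this pair was chosen. The fibroblast median and the median of the pericyte and smooth muscle list were higher too, at 0.29 and 0.22. The difference therefore speaks only against a lower share with fixed proportions, and does not decide on a lower share as such. A smaller share together with shifts among the other cell types stays open. If macrophages alone rose besides, fibroblast and endothelial markers would move alike, but their medians were 0.29 and -0.12. The difference of that pair was not tested. Genotype and lane cannot be told apart with 1 library each, nor can loss of D3B and the Cre transgene. A difference due to the knockout is therefore a hypothesis that may account for part or all of the -0.26.

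White adipocyte-associated, macrophage and matrix genes were higher. The length and GC trend is argued against. After its removal the lowest of the 3 medians, that of the matrix genes, was 0.38 against random lists of -0.07 to 0.08. The same macrophage to endothelial difference of 0.74 speaks only against a lower share of brown adipocytes with other cell types in fixed proportions. A lower share as such stays open. White fat attached to the knockout tissue may raise white adipocyte genes, and it would bring Cfd along with Lep, but the Cfd ratio was 0.297 (0.287 to 0.308). Cfd was at 1591 FPKM in the control library, and values from bulk tissue do not show which cells made it. A drop within brown adipocytes could hide such a contribution. Attached white fat therefore cannot be told apart from altered brown adipocytes here. This holds even for the most abundant list members, Sncg at 480 against 296 FPKM and Lep at 256 against 128 FPKM. A shift of knockout brown adipocytes towards white adipocyte genes, with more macrophages, is an untested hypothesis.

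Immediate early genes were lower while clock and glucocorticoid-responsive genes were shifted. The length and GC trend is argued against, as the immediate early median was -0.48 after its removal with random lists at -0.10 to 0.11. A different time of day at collection could shift all of these, and clock genes that peak with Per and Dbp exceeded those that peak with Arntl by 0.32, but this lay within the range of random pairs of lists, just under its upper bound of 0.33 (percentile 96.97). By the bound first set for this test the explanation would be excluded, but that reading was dropped after the value was seen, because it lies so close to the bound with 5 genes in the Arntl arm, and the time of day stays open. Higher glucocorticoid exposure before collection is a candidate explanation for the glucocorticoid-responsive genes. Whether it would also lower immediate early genes or shift clock genes was not tested. The 20 members of the glucocorticoid list whose values had not been seen had a median of 0.11 at percentile 99.6, against random lists of -0.17 to 0.07. This result could have failed to appear, but it is weak evidence for that exposure. Of the 39 lists fixed before that had a percentile, 12 also lay above the range of random lists. Of 100 simulated lists without a shift, 9 lay outside that range on either side. Those held random genes with counting error alone, so 9 of 100 is not the rate for real lists. Whether handling, time of day or genotype would be behind a higher exposure was not tested.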
